A study of Homo sapiens with 21 samples.

How the data were processed

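The libraries came from U87MG cells in 3 experiments: FOXO3 activation for 8 h or 16 h against GFP, FOXO3 shRNA against shControl, and 10 µM etoposide for 3 d or 14 d. Groups and replicate numbers were taken from the sample titles, with 3 labelled libraries in each of 7 groups. The labels do not say that replicates were separate cultures, so p-values measure the spread between these libraries, which may be technical. Per the labels' protocols, RNA was extracted with a Qiagen column kit and libraries were built with an NEBNext Ultra kit. Per the submitters' processing notes the tools were Trimmomatic, HISAT2 and StringTie and the genome build was hg19; their versions and the use of strand are not given in the sources used here. Antisense transcripts such as MAP3K4-AS1, IGFL2-AS1 and RUSC1-AS1 therefore cannot be told apart from the genes opposite them and are uncertain.

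The authors deposited 1 table of estimated counts per locus for each experiment, with no normalization. StringTie derives such estimated counts from coverage, and low values piled up at multiples of 4. Loci that the assembly merged over several coding genes held 11.4% of counts in the knockdown table, 12.3% in the activation table and 14.0% in the senescence table, so genes in them, such as KRT5 and KRT14, which share loci with other keratins, are uncertain. The loci of ESM1, IRS2, NYAP2, JAG1, RPS6, RPL4 and RPS3 also hold other annotated genes and are uncertain to that extent. Loci without a gene name held 0.396%, 0.454% and 0.622%. Ribosomal protein genes have many pseudogenes that can share reads with them, and FOXO3 shares reads with its near-identical copy FOXO3B. Symbols, gene types and transcript lengths came from GENCODE release 29 by gene identifier, and no coordinates were used because the builds differ. The senescence table also held 3 columns of per-sample values that match no labelled sample and were not used.

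Values were rounded to whole numbers and tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 (robust fit, TMM scaling, low counts removed by filterByExpr, two-sided), with Benjamini-Hochberg adjustment and a threshold of 0.05. Each table was fitted on its own, and the 9 activation libraries shared 1 fit. All adjusted p-values of single genes are from this test unless another is named. The SE of a log2 fold change was taken as its size divided by the square root of the F statistic, which is approximate. CPM used TMM-scaled library sizes, and principal components were computed per table on log2 CPM with a prior count of 2. The FOXO3 shRNA libraries numbered 1 and 2 held identical values and were counted once, which left 2 libraries against 3 where 3 against 3 had been planned.

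Gene lists numbered 26 and were fixed before the data were examined: FOXO targets, insulin and growth factor signalling, DNA replication, mitosis, p53 targets, secreted factors of senescence, interferon response, cholesterol synthesis and uptake, integrated stress and unfolded protein response, autophagy, lysosome, nuclear-encoded respiratory chain, ribosome assembly, glycolysis and hypoxia, antioxidant defence, homologous recombination, extracellular matrix, Notch and BMP response, markers of astrocytes, neurons, epithelia, blood cells and fibroblasts, mitochondrially encoded transcripts, ribosomal proteins and immediate-early genes. Lists with at least 5 tested members were tested with camera of limma 3.58.1 at a preset correlation of 0.01, with an estimated correlation, and with fry, adjusted over the lists within a comparison. A list member whose locus was merged over several coding genes was not tested. Mitochondrially encoded transcripts had too few tested members for a test in any comparison.

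Genes were named by a rule fixed before the data were examined: a few genes per experiment, the 8 largest rises and falls among called genes of mean CPM of at least 5 whose groups did not overlap, leaving out clone and pseudogene names, and up to 4 called members per list. Pseudogenes were first recognised by symbols ending in P and a digit, and after values were seen by annotated gene type; 7 of the 80 genes named by size entered through this change, namely IGFBP1 in the 3 activation comparisons, DUSP7 at 8 h, DEPP1 at 16 h, and NYAP2 and MMP7 after knockdown. Among list examples, those whose calls held when single libraries were left out were preferred after values were seen. TXNIP, one of the fixed genes, was not analysed here because no locus of that name was used, and CDKN2A and CDKN2B fell below the low-count filter in the senescence table. A gene that the rule named by size at 8 h is not reported here.

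Alternatives fixed beforehand were DESeq2 1.42.0 size factors in edgeR, the DESeq2 Wald test, no low-count filter, a replicate block, each library left out in turn, loci with a gene symbol only, a minimum of 2-fold, and a fit of the compared groups alone. Chosen after seeing the data were values divided by 4, the 6 knockdown libraries as deposited, another numbering of the identical library in the block, removal of a loess trend (span 0.5) of expression with transcript length, and 14 d replicate 1 alone. Loci called at 8 h and 16 h were tested as sets in the other tables, with FOXO3 and FOXO3B left out, with overlaps by Fisher's exact test, and agreement between the times was set against 20 simulations of unchanged groups.

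The scripts were tested on simulated counts with 200 loci changed per comparison, and a list of 30 more loci shifted by 0.5 on the log2 scale. Far fewer loci changed there than were called in the data, which makes the adjusted threshold stricter. The rates below therefore do not give the power or the false calls of the real comparisons. At 1.5-fold and 2-fold, the test called 21% and 62% of changed loci for 8 h against GFP (false calls 8.42%), 25% and 75% for 16 h (5.45%), 21% and 59% for 16 h against 8 h (6.82%), 14% and 66% for knockdown (8.05%) and 4% and 39% for senescence (12.2%). Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.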

Results

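RNA sequencing was carried out on U87MG, an established human glioblastoma cell line, in 3 experiments on FOXO3, a forkhead transcription factor held in check by growth factor and insulin signalling. In the activation experiment (9 libraries), doxycycline switched on FOXO3 for 8 h or 16 h, or green fluorescent protein (GFP) as the control, after lentiviral delivery. In the knockdown experiment (6 libraries), cells infected with lentivirus for a short hairpin RNA (shRNA) against FOXO3 were set against a group labelled shControl. In the senescence experiment (6 libraries), 10 µM etoposide, a topoisomerase II poison that breaks DNA, was applied for 3 d or 14 d. Each group held 3 labelled libraries. Summed estimated counts per library ranged from 71673242 to 123255735 in the activation table, 161478544 to 209546176 in the knockdown table and 145767333 to 171816110 in the senescence table. Levels below are CPM, the counts scaled by library size, as mean ± SD over libraries, and log2 fold changes carry their standard error (SE). A value with no unit after a gene name is its log2 fold change ± SE, and n = 3 libraries per group unless stated.

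The 8 h libraries against GFP ask which transcripts change early after FOXO3 is switched on. FOXO3 itself stood at 37485 ± 3700.3 CPM against 117 ± 4.84 in the GFP libraries, a log2 fold change of 8.32 ± 0.24 (adjusted p = 9.27e-08), with reads of the introduced copy and of the cell's own gene counted together. IGFBP1, a secreted binder of insulin-like growth factors, rose from 10.9 ± 0.269 to 662 ± 29.6 CPM. Among genes described as FOXO targets, 25 rose and 1 fell of 36 (27 and 1 adjusted over the list alone). FOXO targets passed camera at adjusted p = 6.15e-33 and had adjusted p = 0.0275 with an estimated correlation. DEPP1, a FOXO-induced regulator of autophagy, rose 56.2-fold, PIK3IP1, an inhibitor of phosphoinositide 3-kinase, 19.3-fold and PDK4, a kinase that holds pyruvate dehydrogenase inactive, 15.8-fold. CCNE1, a cyclin gene of S phase entry, fell from 9.73 ± 0.389 to 2.99 ± 0.237 CPM.

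The FOXO target list had a median log2 fold change of 1.25. CDKN1B, which encodes the cell cycle inhibitor p27, rose from 57.8 ± 1.55 to 241 ± 6.16 CPM (log2 fold change 2.06 ± 0.10, adjusted p = 3.89e-07), and SESN3, a sestrin that restrains mTORC1, from 11.3 ± 0.360 to 166 ± 4.95 CPM (3.87 ± 0.090, adjusted p = 5.17e-09). PIK3IP1 reached 60.1 ± 20.4 CPM from 3.11 ± 0.349 (4.27 ± 0.39, adjusted p = 1.05e-04). CITED2, a partner of CBP and p300, had a log2 fold change of 4.36 ± 0.52, DEPP1 of 5.81 ± 0.17 and PDK4 of 3.98 ± 0.13 (adjusted p of at most 6.14e-04). BCL2L11, the pro-apoptotic BIM gene, missed the threshold at 14.1 ± 6.28 against 6.66 ± 2.06 CPM (1.08 ± 0.36, adjusted p = 0.0502), and passed it without replicate 2 of 8 h (adjusted p = 0.00175), with the DESeq2 Wald test (0.004), with DESeq2 size factors in edgeR (0.0483), over loci with a gene symbol alone (0.0463) and with values divided by 4 (0.0402; range over the alternatives 0.00175 to 0.152). CCND1, which encodes cyclin D1, stood at 163 ± 101 against 117 ± 13.1 CPM (adjusted p = 0.403) and MYC at 11.5 ± 1.45 against 12.8 ± 2.37 CPM (adjusted p = 0.694), neither beyond the spread between libraries. In insulin and growth factor signalling, 13 rose and 1 fell of 22 (15 and 1 adjusted over the list alone). The signalling list passed camera at adjusted p = 1.38e-09 and had adjusted p = 0.0461 with an estimated correlation. The adaptor IRS2 had a log2 fold change of 3.65 ± 0.22, the kinase subunit PIK3CA of 2.47 ± 0.12 and the receptor IGF1R of 2.29 ± 0.14.

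Of DNA replication genes, 0 rose and 13 fell of 34 (0 and 13 adjusted over the list alone). Replication genes passed camera at adjusted p = 0.00160 and had adjusted p = 0.312 with an estimated correlation. Members included CCNE1 (-1.70 ± 0.17), CCNE2 (-1.43 ± 0.17), the repressor E2F8 (-1.35 ± 0.19) and the licensing factor CDT1 (-1.31 ± 0.15). In ribosome assembly, 1 rose and 13 fell of 28 (1 and 16 adjusted over the list alone). Ribosome assembly genes passed camera at adjusted p = 6.85e-04 and had adjusted p = 0.129 with an estimated correlation. NOP2, a methyltransferase of ribosomal RNA, had a log2 fold change of -0.95 ± 0.090 and the RNA polymerase I subunit POLR1B of -0.72 ± 0.14. The matrix list moved the other way: 20 rose and 2 fell of 35 (20 and 2 adjusted over the list alone). Matrix genes passed camera at adjusted p = 6.40e-04 and had adjusted p = 0.227 with an estimated correlation. Members included the proteoglycans DCN (5.67 ± 0.51) and LUM (1.41 ± 0.19) and the collagen gene COL5A2 (1.61 ± 0.11). Of the markers of fibroblasts, another cell type, 7 rose and 1 fell of 14 (7 and 1 adjusted over the list alone). Fibroblast markers passed camera at adjusted p = 0.01005 and had adjusted p = 0.228 with an estimated correlation. TWIST1, a mesenchymal transcription factor, had a log2 fold change of 2.32 ± 0.26 and FAP of 0.80 ± 0.070. Among astrocyte markers 5 rose and 0 fell of 14 (5 and 0 adjusted over the list alone). Astrocyte markers passed camera at adjusted p = 0.0248 and had adjusted p = 0.189 with an estimated correlation. Members included SOX9 (2.65 ± 0.18) and GLUL, which encodes glutamine synthetase (1.87 ± 0.077). Of immediate-early genes, which respond within minutes to serum and handling, 14 rose and 3 fell of 26 (15 and 3 adjusted over the list alone). Immediate-early genes passed camera at adjusted p = 1.29e-05 and had adjusted p = 0.303 with an estimated correlation. Members included NR4A2 (3.84 ± 0.33), EGR2 (3.17 ± 0.28), FOS (3.14 ± 0.23) and EGR1 (2.76 ± 0.12).

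By size alone, the largest rises at 8 h also included those of NDST4, an enzyme that modifies heparan sulfate (8.93 ± 0.49), ESM1, a secreted proteoglycan (7.53 ± 0.73), NXPE2 (7.20 ± 0.40), the matrix protein gene VIT (7.08 ± 0.24) and ABCA6, a transporter of the ABC family (6.93 ± 0.55). ESM1 stood at 0.247 ± 0.278 and ABCA6 at 0.352 ± 0.245 CPM in the GFP libraries. The log2 fold change of ESM1 was 6.94 without GFP replicate 1 and 8.86 without GFP replicate 2, and that of ABCA6 7.55 without GFP replicate 2. The largest falls belonged to PPARGC1B, a coactivator of mitochondrial genes (-2.76 ± 0.31), AHDC1 (-2.36 ± 0.16), the circadian repressor CIART (-2.34 ± 0.24), DUSP7, a phosphatase of MAP kinases (-2.26 ± 0.14), the ephrin receptor EPHA2 (-2.18 ± 0.098), the homeobox gene DLX1 (-2.11 ± 0.23), the receptor GPR3 (-2.04 ± 0.21) and the adhesion protein gene LRFN4 (-2.03 ± 0.15). Each of these rises and falls had an adjusted p of at most 1.90e-04.

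Over all 21255 loci tested at 8 h, 3516 rose and 3169 fell (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). Lists of mitotic, p53 target, senescence-associated secreted factor, interferon, cholesterol, stress response, autophagy, lysosome, respiratory chain, glycolysis, antioxidant, homologous recombination, Notch and BMP, neuron, epithelial, blood cell and ribosomal protein genes did not pass (camera adjusted p from 0.0512 to 0.918). Among them, on the interferon list 7 rose and 5 fell of 33 (7 and 5 adjusted over the list alone), and on the stress response list 6 rose and 10 fell of 30 (6 and 11 adjusted over the list alone). Of epithelial markers 0 rose and 0 fell of 8 (0 and 0 adjusted over the list alone), and of blood cell markers 1 rose and 1 fell of 10 (1 and 1 adjusted over the list alone). The secreted factor list passed without 8 h replicate 2 (0.0390) or GFP replicate 3 (0.0341; range over the alternatives 0.0341 to 0.160). The antioxidant list passed without 8 h replicate 2 (0.0373) or 3 (0.0369) or GFP replicate 1 (0.0280) or 2 (0.0423) and with DESeq2 size factors (0.0488; range 0.0280 to 0.0894), and the ribosomal protein list without GFP replicate 1 (0.0402; range 0.0402 to 0.375). The median, mean and test of the p53 target, neuron and blood cell lists differed in sign, and transcripts of the mitochondrial genome had only 2 tested members and no test.

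**Figure D1:**
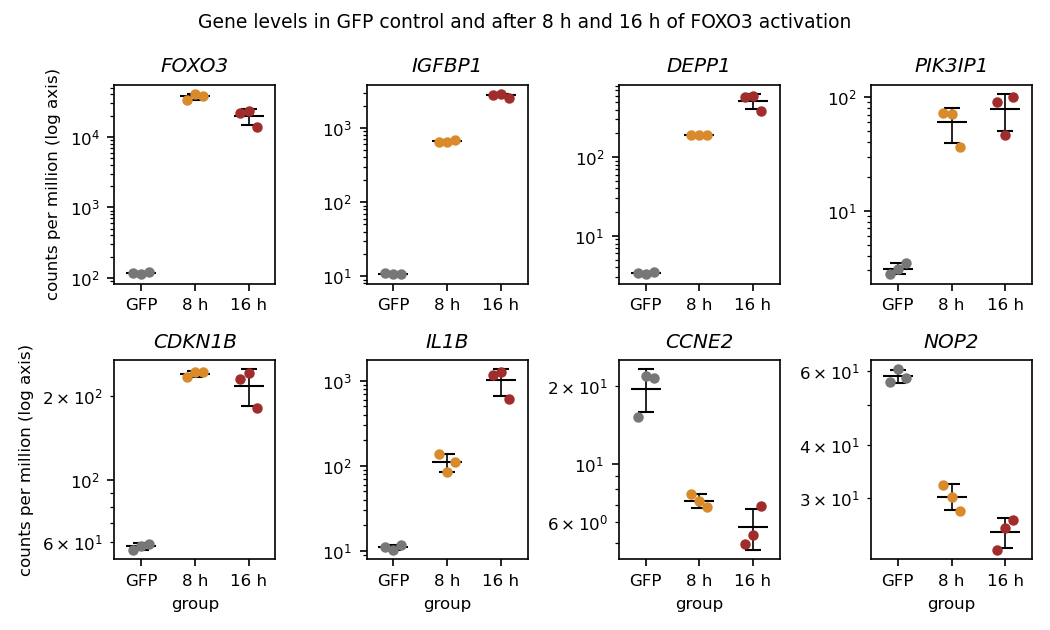
Levels of 8 genes in CPM on a log axis, in GFP control libraries and after 8 h and 16 h of FOXO3 activation, with a point for each library and bars for the mean ± SD (n = 3). FOXO3, IGFBP1, DEPP1, PIK3IP1, CDKN1B and IL1B lie above the GFP libraries at both times, and CCNE2 and NOP2 lie below.

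The 16 h libraries ask the same question later after induction. FOXO3 stood at 19545 ± 5033 CPM, 167-fold over GFP (log2 fold change 7.38 ± 0.23, adjusted p = 1.36e-07); it took 2.08%, 2.16% and 1.37% of counts in replicates 1, 2 and 3. Replicate 3 of 16 h stood apart on the leading principal components, at -17.2 and 24.2 against -42.4 and 68.3 for replicate 1 and -40.8 and 61.3 for replicate 2. IGFBP1 rose 253-fold to 2743 ± 165 CPM. IL1B, the gene of the inflammatory cytokine interleukin 1 beta, rose from 11.1 ± 0.798 to 1014 ± 349 CPM, and IL6 from 5.24 ± 2.07 to 50.2 ± 24.7 CPM. Among replication genes 0 rose and 29 fell of 34 (0 and 30 adjusted over the list alone). Replication genes passed camera at adjusted p = 3.87e-12 and had adjusted p = 0.0426 with an estimated correlation.

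Of FOXO targets 25 rose and 2 fell of 36 (27 and 2 adjusted over the list alone). FOXO targets passed camera at adjusted p = 6.59e-35 and had adjusted p = 0.0225 with an estimated correlation. DEPP1 had a log2 fold change of 7.27 ± 0.19 and CITED2 of 3.89 ± 0.51; without replicate 1 of 16 h the value for CITED2 was 3.15. CDKN1B stood at 218 ± 32.6 CPM (log2 fold change 1.91 ± 0.10, adjusted p = 7.65e-07), SESN3 at 151 ± 15.8 CPM (3.73 ± 0.089, adjusted p = 1.29e-08) and PIK3IP1 at 78.7 ± 28.5 CPM (4.66 ± 0.40, adjusted p = 8.04e-05). BCL2L11, at 12.1 ± 0.336 CPM (adjusted p = 0.106), CCND1, at 90.3 ± 13.6 CPM (adjusted p = 0.528), and MYC, at 13.9 ± 5.23 CPM (adjusted p = 0.782), did not pass the threshold. BCL2L11 passed it by DESeq2 (adjusted p = 0.0281) and in an edgeR fit of the 16 h and GFP libraries alone (adjusted p = 0.0210; range over the alternatives 0.0210 to 0.267). In insulin and growth factor signalling 14 rose and 5 fell of 22 (14 and 5 adjusted over the list alone). The signalling list passed camera at adjusted p = 3.74e-10 and had adjusted p = 0.0228 with an estimated correlation. IRS2 had a log2 fold change of 3.55 ± 0.22, the kinase SGK1 of 2.66 ± 0.25 and IGF1R of 2.56 ± 0.14.

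Replication genes that fell included CCNE2 (-1.77 ± 0.17), E2F8 (-1.57 ± 0.19) and CDT1 (-1.37 ± 0.15). Of homologous recombination genes 4 rose and 18 fell of 31 (4 and 20 adjusted over the list alone). Recombination genes passed camera at adjusted p = 1.86e-04 and had adjusted p = 0.0228 with an estimated correlation. The recombination factors RAD54L had a log2 fold change of -1.11 ± 0.13 and XRCC2 of -1.08 ± 0.15. In ribosome assembly 1 rose and 21 fell of 28 (1 and 21 adjusted over the list alone). Ribosome assembly genes passed camera at adjusted p = 1.38e-08 and had adjusted p = 0.0225 with an estimated correlation. NOP2 had a log2 fold change of -1.23 ± 0.090 and POLR1B of -1.06 ± 0.14. On the mitotic list 3 rose and 20 fell of 41 (3 and 23 adjusted over the list alone). The mitotic list passed camera at adjusted p = 8.02e-04 and had adjusted p = 0.392 with an estimated correlation. The kinesin KIF2C (-0.75 ± 0.064) and the lamin LMNB1 (-0.89 ± 0.14) fell while the kinesin KIF20B rose (2.23 ± 0.16). Of cholesterol synthesis and uptake genes 0 rose and 9 fell of 25 (0 and 9 adjusted over the list alone). Cholesterol genes passed camera at adjusted p = 0.0150 and had adjusted p = 0.392 with an estimated correlation. Members included SREBF1, a transcription factor of lipid synthesis (-1.04 ± 0.14), and FASN, the fatty acid synthase gene (-0.94 ± 0.074).

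Among secreted factors described in senescent cells 18 rose and 8 fell of 38 (18 and 8 adjusted over the list alone). Secreted factors passed camera at adjusted p = 1.32e-04 and had adjusted p = 0.392 with an estimated correlation. IL1B had a log2 fold change of 6.51 ± 0.35, IL6 of 3.26 ± 0.47, the chemokine CXCL8 of 3.45 ± 0.56 and IGFBP3 of 2.80 ± 0.22. Of autophagy genes 16 rose and 3 fell of 31 (16 and 3 adjusted over the list alone). Autophagy genes passed camera at adjusted p = 0.00252 and had adjusted p = 0.131 with an estimated correlation. RB1CC1, which starts autophagosome formation, rose (1.13 ± 0.065) and TFEB, a transcription factor of lysosomal genes, fell (-1.27 ± 0.20). On the lysosome list 10 rose and 1 fell of 29 (11 and 1 adjusted over the list alone). Lysosomal genes passed camera at adjusted p = 0.0159 and had adjusted p = 0.121 with an estimated correlation. Members included the proton pump subunit ATP6V0D2 (2.84 ± 0.099) and the protease CTSB (1.05 ± 0.094). Of immediate-early genes 16 rose and 3 fell of 26 (17 and 3 adjusted over the list alone). Immediate-early genes passed camera at adjusted p = 3.61e-10 and had adjusted p = 0.131 with an estimated correlation. NR4A2 had a log2 fold change of 4.15 ± 0.34 and FOS of 3.36 ± 0.23. For antioxidant genes 12 rose and 3 fell of 27 (13 and 3 adjusted over the list alone). Antioxidant genes passed camera at adjusted p = 0.0438 and had adjusted p = 0.392 with an estimated correlation. HMOX1, the heme oxygenase gene, had a log2 fold change of 2.01 ± 0.21. This call was lost without replicate 2 of 16 h (camera adjusted p = 0.0558) or GFP replicate 3 (0.0613) and with values divided by 4 (0.0687; range over the alternatives 0.00753 to 0.0687). Of ribosomal protein genes, whose level can also vary with RNA quality, 14 rose and 0 fell of 40 (14 and 0 adjusted over the list alone). Ribosomal protein genes passed camera at adjusted p = 0.0183 and had adjusted p = 0.646 with an estimated correlation. RPS4X had a log2 fold change of 0.50 ± 0.094. Leaving out the same libraries ended this call too (camera adjusted p of 0.0569 and 0.0613; range 9.92e-04 to 0.0613). With the length trend removed, an alternative chosen after seeing the data, neither list passed (camera adjusted p = 0.0608 for both).

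The largest rises at 16 h were those of IGFBP1 (7.98 ± 0.084), FOXO3, DEPP1, NXPE2 (7.21 ± 0.40), ABCA6 (7.04 ± 0.55; 7.66 without GFP replicate 2), VIT (6.72 ± 0.24), IL1B and ESM1 (6.36 ± 0.71; 5.77 without GFP replicate 1 and 7.70 without GFP replicate 2). The largest falls were those of PPARGC1B (-2.07 ± 0.30), PWWP2B (-1.95 ± 0.12), the corepressor gene BCOR (-1.89 ± 0.20), CHAC1, a glutathione-degrading enzyme of the stress response (-1.88 ± 0.25), APLN, which encodes the peptide apelin (-1.84 ± 0.16), GPR3 (-1.84 ± 0.21), the stress gene GADD45B (-1.82 ± 0.35) and the transcription factor NFATC2 (-1.80 ± 0.27), with adjusted p of at most 0.00515 for each of the named changes. In total 3662 loci rose and 3238 fell of 21255 (edgeR, adjusted p under 0.05). Without replicate 3 of 16 h 6889 were called, and 5552 and 5793 without replicate 1 or 2.

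Lists of p53 target, interferon, stress response, respiratory chain, glycolysis, matrix, Notch and BMP, astrocyte, neuron, epithelial, blood cell and fibroblast genes did not pass at 16 h (camera adjusted p from 0.0574 to 0.998), with sign differences between median, mean and test for p53 target, interferon, matrix and epithelial genes. On the interferon list 9 rose and 8 fell of 33 (11 and 8 adjusted over the list alone), and on the stress response list 6 rose and 10 fell of 30 (6 and 10 adjusted over the list alone). Of epithelial markers 1 rose and 0 fell of 8 (0 and 0 adjusted over the list alone), and of blood cell markers 1 rose and 1 fell of 10 (1 and 1 adjusted over the list alone). SESN1 (1.49 ± 0.072) and TP53INP1 (1.92 ± 0.081) rose on the p53 list, and SAMD9 (2.39 ± 0.072) and IFIT3 (2.03 ± 0.087) on the interferon list. SESN1 and TP53INP1 are also on the FOXO target list. Leaving out single libraries brought calls of the stress response list without GFP replicate 1 (camera adjusted p = 0.0119, range over the alternatives 0.0119 to 0.242), the Notch and BMP list without 16 h replicate 3 (0.0262, range 0.0262 to 0.319) and astrocyte markers without 16 h replicate 1 (0.0436) or with values divided by 4 (0.0352, range 0.0352 to 0.0843). Fibroblast markers passed without 16 h replicate 2 (0.0474) or 3 (0.00945) or GFP replicate 1 (0.0297) or with values divided by 4 (0.0300; range 0.00945 to 0.0859).

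The comparisons at 8 h and 16 h share their GFP libraries, so part of their likeness may arise from those controls. The sample titles give no induction time for GFP, so differences between 8 h and 16 h may also reflect time in doxycycline or in culture. The 2 comparisons shared 2577 rises, against 606 for independent lists, and 2048 falls, against 483. Greater power for abundant loci can also raise such overlaps. Across genes, which are not independent replicates, the log2 fold changes correlated with r = 0.812 (simulated unchanged groups against the same controls gave 0.508) and a covariance of 1.21 (simulated 0.171), and 78.6% had the same sign (simulated 66.8%). Simulated groups shared 0 calls at most in 20 draws; splitting 3 controls leaves fewer than 2 in an arm, so part of the excess may come from them.

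Tested directly between the times, IL1B was 9.15-fold higher at 16 h than at 8 h and IGFBP1 4.15-fold, while FOXO3 fell by 0.94 on the log2 scale (SE 0.17, adjusted p = 0.00878). EPHA5, an ephrin receptor, fell from 100.1 ± 6.99 to 20.4 ± 2.39 CPM and RORB, a nuclear receptor, from 37.1 ± 6.07 to 8.31 ± 1.68 CPM. Of matrix genes 0 rose and 16 fell of 35 (0 and 18 adjusted over the list alone). Matrix genes passed camera at adjusted p = 1.67e-11 and had adjusted p = 0.105 with an estimated correlation. CDKN1B, BCL2L11, PIK3IP1, SESN3, CCND1 and MYC had log2 differences of -0.15 ± 0.097, -0.22 ± 0.35, 0.39 ± 0.34, -0.14 ± 0.080, -0.85 ± 0.38 and 0.27 ± 0.25, none called (adjusted p of 0.393, 0.762, 0.536, 0.320, 0.214 and 0.559).

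Matrix genes lower at 16 h included LOXL1, a collagen cross-linking enzyme (-1.08 ± 0.076), COL5A1 (-0.85 ± 0.066) and COL5A2 (-0.94 ± 0.10). Of replication genes 1 rose and 15 fell of 34 (1 and 21 adjusted over the list alone). Replication genes passed camera at adjusted p = 3.23e-08 and had adjusted p = 0.163 with an estimated correlation. Members included the helicase BRIP1 (-0.88 ± 0.097) and the licensing helicase subunit MCM2 (-0.70 ± 0.10). On the mitotic list 0 rose and 11 fell of 41 (0 and 14 adjusted over the list alone). The mitotic list passed camera at adjusted p = 0.00402 and had adjusted p = 0.629 with an estimated correlation. CCNA2 had a log2 fold change of -0.61 ± 0.074. On the homologous recombination list 0 rose and 5 fell of 31 (0 and 5 adjusted over the list alone). Recombination genes passed camera at adjusted p = 0.00411 and had adjusted p = 0.118 with an estimated correlation. ATM, the kinase that senses DNA breaks, had a log2 fold change of -0.80 ± 0.10 and BARD1 of -0.68 ± 0.12. In ribosome assembly 1 rose and 8 fell of 28 (1 and 15 adjusted over the list alone). Ribosome assembly genes passed camera at adjusted p = 0.00411 and had adjusted p = 0.163 with an estimated correlation. Among secreted factors of senescence 11 rose and 5 fell of 38 (12 and 6 adjusted over the list alone). Secreted factors passed camera at adjusted p = 0.00111 and had adjusted p = 0.613 with an estimated correlation. Members included the cytokine genes CSF3 (2.25 ± 0.37) and LIF (1.71 ± 0.21). Of autophagy genes 9 rose and 0 fell of 31 (9 and 0 adjusted over the list alone). Autophagy genes passed camera at adjusted p = 0.0205 and had adjusted p = 0.313 with an estimated correlation. The cargo receptor SQSTM1 had a log2 fold change of 0.61 ± 0.054. Of lysosomal genes 5 rose and 0 fell of 29 (6 and 0 adjusted over the list alone). Lysosomal genes passed camera at adjusted p = 0.0285 and had adjusted p = 0.188 with an estimated correlation. ATP6V0D2 had a log2 fold change of 0.82 ± 0.093 and CTSB of 0.55 ± 0.093. Among neuron markers 1 rose and 4 fell of 11 (2 and 5 adjusted over the list alone). Neuron markers passed camera at adjusted p = 0.0433 and had adjusted p = 0.195 with an estimated correlation. MAP2 had a log2 fold change of -1.29 ± 0.17 and SNAP25 of -1.18 ± 0.16; their median was -0.33 and their mean 0.32. Of immediate-early genes 6 rose and 1 fell of 26 (8 and 1 adjusted over the list alone). Immediate-early genes passed camera at adjusted p = 0.0196 and had adjusted p = 0.649 with an estimated correlation. DUSP1 had a log2 fold change of 1.14 ± 0.11 and FOSL1 of 0.91 ± 0.12.

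The largest rises between the times were those of IL1B (3.19 ± 0.30), TPPP, which bundles microtubules (2.92 ± 0.18), IL6 (2.27 ± 0.44), CSF3, IGFBP1 (2.05 ± 0.064), the carnosine synthase gene CARNS1 (2.00 ± 0.18), CYP24A1, which degrades vitamin D (1.98 ± 0.24), and the antisense transcript MAP3K4-AS1 (1.79 ± 0.26). The largest falls were those of ANKRD30B (-2.86 ± 0.14), the adhesion protein genes FLRT3 (-2.81 ± 0.41) and SLITRK6 (-2.07 ± 0.24), EPHA5 (-2.29 ± 0.10), RORB (-2.16 ± 0.23), TMEM74 (-2.12 ± 0.15), NDST4 (-2.00 ± 0.31) and SNX22 (adjusted p = 0.0394). SNX22 measured 25.9, 0.178 and 25.0 CPM in 8 h replicates 1, 2 and 3, against 0.159 ± 0.0285 at 16 h. Its call was lost without the low-count filter (adjusted p = 0.0968), with both groups fitted alone (0.0648), and without any 16 h library or 8 h replicate 1 or 3 (0.134, 0.139, 0.101, 0.0953 and 0.105, range 5.08e-06 to 0.139). That of IL6 was lost without 8 h replicate 1, 2 or 3 (0.0563, 0.0684 and 0.0670, range 3.58e-05 to 0.0684).

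Between the times 1403 loci rose and 1368 fell of 21255 (edgeR, adjusted p under 0.05). The total of 2771 became 1726, 1817 and 2947 without replicate 1, 2 or 3 of 16 h and 1801, 1597 and 1629 without replicate 1, 2 or 3 of 8 h. Without replicate 1 of 16 h the autophagy, lysosome, neuron and immediate-early lists lost their calls (camera adjusted p of 0.0667, 0.0760, 0.0760 and 0.0760), and without replicate 2 the neuron and immediate-early lists (0.0924 for both; range over the alternatives 0.0107 to 0.0667, 0.00931 to 0.0760, 0.00148 to 0.0924 and 2.62e-05 to 0.0924 for the 4 lists). The remaining lists did not pass (camera adjusted p from 0.145 to 0.980): FOXO target, insulin and growth factor signalling, p53 target, interferon, cholesterol, stress response, respiratory chain, glycolysis, antioxidant, Notch and BMP, astrocyte, epithelial, blood cell, fibroblast and ribosomal protein genes. Among these, on the interferon list 2 rose and 2 fell of 33 (3 and 5 adjusted over the list alone), and on the stress response list 1 rose and 4 fell of 30 (1 and 4 adjusted over the list alone). Of epithelial markers 0 rose and 0 fell of 8 (0 and 0 adjusted over the list alone), and of blood cell markers 0 rose and 0 fell of 10 (0 and 0 adjusted over the list alone). Median, mean and test differed in sign for insulin and growth factor signalling and for astrocyte, epithelial and blood cell markers. The ribosomal protein list passed without 16 h replicate 3 (camera adjusted p = 0.0278, range over the alternatives 0.0278 to 0.559).

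The knockdown comparison asks what changes when FOXO3 is reduced. FOXO3 measured 38.3 CPM in the FOXO3 shRNA library deposited under numbers 1 and 2 and 41.0 in the other, against 56.0, 55.0 and 60.2 CPM in the shControl libraries, a log2 fold change of -0.53 ± 0.069 (adjusted p = 0.00148). Of mitotic genes 0 rose and 40 fell of 40 (0 and 40 adjusted over the list alone). The mitotic list passed camera at adjusted p = 7.66e-33 and had adjusted p = 0.0758 with an estimated correlation. CCNB1, the mitotic cyclin B1 gene, dropped from 247 ± 2.33 to 25.6 ± 1.62 CPM and MCM2, a replication gene, from 237 ± 2.85 to 48.3 ± 3.88 CPM (n = 2 against 3 here and in the following). The collagen gene COL1A2 rose from 391 ± 13.3 to 5854 ± 188 CPM and SCG2, which encodes the granule protein secretogranin II, from 0.542 ± 0.111 to 685 ± 463 CPM.

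The FOXO3 shRNA libraries deposited under numbers 1 and 2 held identical values and were counted as 1 sample. Mitotic genes had a median log2 fold change of -2.43, including CDC20, an activator of the anaphase ligase (-2.97 ± 0.064), CCNB1 (-3.27 ± 0.068) and the transcription factor FOXM1 (-2.86 ± 0.19). Of replication genes 0 rose and 35 fell of 35 (0 and 35 adjusted over the list alone). Replication genes passed camera at adjusted p = 1.64e-21 and had adjusted p = 0.0758 with an estimated correlation. MCM2 had a log2 fold change of -2.30 ± 0.072, MCM4 of -2.01 ± 0.087 and the nuclease EXO1 of -2.29 ± 0.067. Of homologous recombination genes 0 rose and 29 fell of 31 (0 and 31 adjusted over the list alone). Recombination genes passed camera at adjusted p = 6.05e-13 and had adjusted p = 0.0758 with an estimated correlation. The helicase BLM had a log2 fold change of -2.41 ± 0.18 and FANCD2 of -2.27 ± 0.067. In ribosome assembly 1 rose and 26 fell of 29 (1 and 26 adjusted over the list alone). Ribosome assembly genes passed camera at adjusted p = 6.13e-11 and had adjusted p = 0.0758 with an estimated correlation. ODC1, the enzyme that starts polyamine synthesis, had a log2 fold change of -3.24 ± 0.075 and FBL, fibrillarin, of -1.41 ± 0.14. Of ribosomal protein genes 0 rose and 39 fell of 39 (0 and 39 adjusted over the list alone). Ribosomal protein genes passed camera at adjusted p = 8.78e-19 and had adjusted p = 0.0758 with an estimated correlation. RPL4 had a log2 fold change of -1.82 ± 0.088 and RPS6 of -1.64 ± 0.068. Their median was -1.02, and -0.86 with the trend of expression with transcript length removed. Of respiratory chain genes 0 rose and 21 fell of 31 (0 and 22 adjusted over the list alone). Respiratory chain genes passed camera at adjusted p = 1.60e-04 and had adjusted p = 0.222 with an estimated correlation. The cytochrome gene CYC1 had a log2 fold change of -1.15 ± 0.064.

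Of FOXO target genes 25 rose and 5 fell of 37 (26 and 5 adjusted over the list alone). FOXO targets passed camera at adjusted p = 3.00e-06 and had adjusted p = 0.0758 with an estimated correlation. DEPP1 had a log2 fold change of 4.39 ± 0.12, the ubiquitin ligase gene FBXO32 of 3.73 ± 0.059 and SESN1 of 1.94 ± 0.15. The related factors FOXO1, at 5.98 ± 0.265 against 3.32 ± 0.587 CPM (log2 fold change 0.85 ± 0.17, adjusted p = 0.00806), and FOXO4, at 10.0 ± 0.826 against 5.95 ± 0.715 CPM (0.75 ± 0.13, adjusted p = 0.00497), were higher. Without replicate 3 of FOXO3 shRNA the adjusted p of FOXO1 was 0.0512 (range over the alternatives 4.62e-05 to 0.0512). CDKN1B stood at 82.6 ± 6.11 against 76.0 ± 0.724 CPM (adjusted p = 0.173), CCND1 at 568 ± 152 against 660.3 ± 205 (adjusted p = 0.632) and MYC at 25.2 ± 6.70 against 35.2 ± 13.7 (adjusted p = 0.347), none called. With the length trend removed CDKN1B had adjusted p = 0.00626 (range over its alternatives 0.00626 to 0.615). Of p53 targets 23 rose and 3 fell of 34 (23 and 3 adjusted over the list alone). p53 targets passed camera at adjusted p = 4.46e-07 and had adjusted p = 0.0758 with an estimated correlation. Members included the antiproliferative gene BTG2 (2.87 ± 0.099) and the stress cytokine gene GDF15 (2.40 ± 0.059). Among secreted factors of senescence 21 rose and 7 fell of 37 (22 and 7 adjusted over the list alone). Secreted factors passed camera at adjusted p = 5.41e-04 and had adjusted p = 0.222 with an estimated correlation. The adhesion molecule ICAM1 (4.68 ± 0.12) and CXCL8 (3.87 ± 0.19) rose and the growth factor HGF fell (-3.12 ± 0.065).

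Of matrix genes 26 rose and 2 fell of 34 (27 and 2 adjusted over the list alone). Matrix genes passed camera at adjusted p = 1.15e-12 and had adjusted p = 0.146 with an estimated correlation. COL1A2 had a log2 fold change of 3.90 ± 0.063 and COL3A1 of 5.99 ± 0.36. Among fibroblast markers 10 rose and 1 fell of 13 (10 and 2 adjusted over the list alone). Fibroblast markers passed camera at adjusted p = 3.16e-04 and had adjusted p = 0.0758 with an estimated correlation. COL1A1 had a log2 fold change of 2.63 ± 0.058. Among neuron markers 10 rose and 0 fell of 15 (11 and 0 adjusted over the list alone). Neuron markers passed camera at adjusted p = 3.53e-04 and had adjusted p = 0.0758 with an estimated correlation. The synaptic vesicle gene SYP had a log2 fold change of 5.06 ± 0.12. Of Notch and BMP response genes 11 rose and 2 fell of 24 (11 and 2 adjusted over the list alone). Notch and BMP genes passed camera at adjusted p = 0.00720 and had adjusted p = 0.122 with an estimated correlation. HES1 had a log2 fold change of 2.10 ± 0.12 and JAG1 of 1.47 ± 0.077. Of glycolysis and hypoxia genes 16 rose and 10 fell of 34 (16 and 11 adjusted over the list alone). Glycolysis and hypoxia genes passed camera at adjusted p = 0.0469 and had adjusted p = 0.543 with an estimated correlation. The glucose transporter SLC2A1 had a log2 fold change of 2.19 ± 0.057 and the collagen hydroxylase P4HA1 of 2.85 ± 0.057. This call was lost without replicate 3 of FOXO3 shRNA (camera adjusted p = 0.130) or shControl replicate 1, 2 or 3 (0.137, 0.106 and 0.0952), with values divided by 4 (0.0660) and with all 6 libraries as deposited (0.156; range over the alternatives 0.0242 to 0.156).

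**Figure D2:**
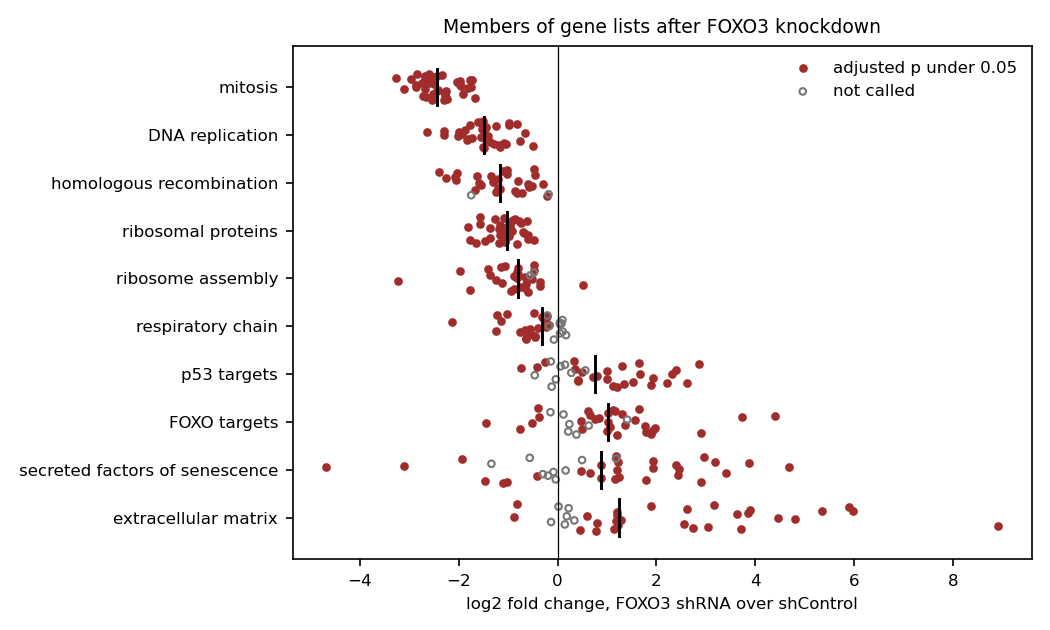
Log2 fold change of FOXO3 shRNA over shControl libraries (n = 2 against 3) for each tested member of 10 gene lists, with filled points for adjusted p under 0.05, open points for genes not called and a bar at the median of each list. The median is -2.43 for mitosis and 1.25 for extracellular matrix.

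By size, the leading rises after knockdown were SCG2 (10.30 ± 0.64; 9.36 without the library deposited under numbers 1 and 2), the matrix protein POSTN (8.92 ± 0.62), the procollagen protease ADAMTS14 (7.70 ± 0.12), BPIFC (7.67 ± 0.43), OLFM2 (7.32 ± 0.44), NYAP2 (7.13 ± 0.16), the matrix protease MMP7 (6.65 ± 0.43) and COL5A3 (6.26 ± 0.15). POSTN rested on 18 counts over the shControl libraries. The leading falls were the interferon-stimulated gene IFI44L (-4.20 ± 0.14), the trypsin gene PRSS3 (-4.16 ± 0.15), SIGLEC15 (-4.11 ± 0.066), the forkhead gene FOXC2 (-3.93 ± 0.092), KCTD4 (-3.85 ± 0.15), LYPD6 (-3.80 ± 0.17), INSYN2B (-3.75 ± 0.099) and TFAM, which maintains mitochondrial DNA (-3.56 ± 0.12), all with adjusted p of at most 2.39e-04. Of 23377 loci tested, 5837 rose and 5876 fell (edgeR, adjusted p under 0.05), and the FOXO3 shRNA libraries held more loci with a count (29776 and 30037) than the shControl libraries (27154, 25920 and 27044). Replicate 2 of shControl stood apart on the second principal component, at 83.4 against -42.0 and -40.5 for the other shControl libraries, and without it 10969 loci were called of 11713 in all.

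Lists of insulin and growth factor signalling, interferon, cholesterol, stress response, autophagy, lysosome, antioxidant, astrocyte, epithelial, blood cell and immediate-early genes did not pass after knockdown (camera adjusted p from 0.0540 to 0.739), with the median and mean of astrocyte markers differing in sign. On the interferon list 7 rose and 14 fell of 34 (7 and 14 adjusted over the list alone), and on the stress response list 12 rose and 11 fell of 32 (12 and 11 adjusted over the list alone). Of epithelial markers 4 rose and 0 fell of 12 (4 and 0 adjusted over the list alone), and of blood cell markers 0 rose and 0 fell of 9 (0 and 0 adjusted over the list alone). Without replicate 3 of FOXO3 shRNA the interferon and cholesterol lists passed (camera adjusted p = 0.0405 for both), and the cholesterol list also without shControl replicate 1 (0.0346) or 3 (0.0451). Epithelial markers passed without the library deposited under numbers 1 and 2 (0.0327) and blood cell markers without shControl replicate 2 (2.24e-04). With the length trend removed the autophagy (0.0313) and lysosome lists (0.0235) passed. Over the alternatives these adjusted p ranged from 0.0405 to 0.156 for interferon, 0.0346 to 0.110 for cholesterol, 0.0327 to 0.132 for epithelial, 2.18e-04 to 0.301 for blood cell, 0.0313 to 0.158 for autophagy and 0.0235 to 0.183 for lysosomal genes.

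Loci called after FOXO3 activation were then read in the knockdown comparison, which uses other libraries. The 2966 loci lower at 16 h had a median log2 fold change of -0.18 under FOXO3 shRNA (camera adjusted p = 0.00567, and adjusted p = 0.140 with an estimated correlation), and 1286 were lower in both, against 868 for independent lists (odds ratio 2.12). Of loci higher at 16 h, 1083 were also higher under FOXO3 shRNA, against 803 (odds ratio 1.69). At 8 h 1018 loci were higher in both, against 758, and 1088 lower in both, against 832 (odds ratios 1.67 and 1.63). Overlaps of opposite direction exceeded independence as well, by less, for loci higher at 16 h and lower under FOXO3 shRNA (979 against 922, Fisher adjusted p = 0.0220) and for loci lower at 8 h and higher under FOXO3 shRNA (789 against 724, adjusted p = 0.00404). Abundant loci have more power, so a part of each excess may come from loci that are easier to call in both. As sets, loci lower at 8 h (camera adjusted p = 0.0835) and loci higher at 8 h and at 16 h (0.660 for both) did not pass. Restricted to loci that activation changed at least 2-fold, those higher at 8 h (median log2 fold change 0.50, camera adjusted p = 0.00180) and at 16 h (0.48, 0.00235) did pass, and the median of those lower at 16 h turned to 0.15 (adjusted p = 0.334).

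The senescence comparison asks what differs between 14 d and 3 d of etoposide; no untreated culture was analysed here, so each value is relative to 3 d. Of cholesterol synthesis and uptake genes 0 rose and 23 fell of 26 (0 and 24 adjusted over the list alone). Cholesterol genes passed camera at adjusted p = 1.10e-39 and had adjusted p = 0.363 with an estimated correlation. HMGCS1, an early enzyme of the pathway, dropped from 396 ± 110.4 to 52.4 ± 0.495 CPM and INSIG1, which retains the SREBP activators, from 760.2 ± 159 to 125 ± 18.8 CPM. The cytokine genes CSF2 and CXCL8 fell 7.50-fold and 1.84-fold. FOXO3 rose from 68.7 ± 4.14 to 102 ± 13.4 CPM (log2 fold change 0.57 ± 0.12, adjusted p = 0.00996), and KRT1, a keratin gene of the skin, differed between the 14 d libraries at 5.00, 97.0 and 94.6 CPM.

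Cholesterol genes had a median log2 fold change of -1.28, with HMGCS1 at -2.92 ± 0.19, INSIG1 at -2.61 ± 0.18, ACAT2 at -2.42 ± 0.15 and the sterol oxidase gene MSMO1 at -2.23 ± 0.13. Among secreted factors of senescence 8 rose and 17 fell of 40 (10 and 17 adjusted over the list alone). Secreted factors passed camera at adjusted p = 5.31e-05 and had adjusted p = 0.363 with an estimated correlation. Members included CSF2 (-2.91 ± 0.19), CCL20 (-2.20 ± 0.22), HGF (-1.81 ± 0.13) and IL11 (-1.76 ± 0.18). IL6 stood at 148 ± 11.0 against 257 ± 33.1 CPM (-0.79 ± 0.12, adjusted p = 0.00320) and CXCL8 at 1209.5 ± 25.0 against 2227 ± 190.1 CPM (-0.88 ± 0.11, adjusted p = 0.00127). CDKN1A, the cell cycle inhibitor p21, was lower at 672 ± 74.6 against 1158 ± 169 CPM (-0.78 ± 0.14, adjusted p = 0.00544), and so was GDF15 at 692 ± 57.4 against 2126 ± 754 CPM (-1.62 ± 0.24, adjusted p = 0.00320). LMNB1, at 5.17 ± 1.69 against 4.23 ± 0.613 CPM (adjusted p = 0.432), and the proliferation marker MKI67, at 25.6 ± 2.81 against 21.6 ± 4.67 CPM (adjusted p = 0.338), were not called. HMGB2, a chromatin protein, was called lower at 26.5 ± 7.74 against 42.6 ± 5.71 CPM (adjusted p = 0.0417) and lost the call without 14 d replicate 1 or 2 (0.118 and 0.138) or 3 d replicate 1, 2 or 3 (0.144, 0.0855 and 0.0717; range over the alternatives 0.00891 to 0.144).

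Of ribosomal protein genes 0 rose and 26 fell of 40 (0 and 37 adjusted over the list alone). Ribosomal protein genes passed camera at adjusted p = 2.79e-13 and had adjusted p = 0.530 with an estimated correlation. RPS3 had a log2 fold change of -1.06 ± 0.14. Their median was -0.73, and -0.63 with the length trend removed. Of respiratory chain genes 0 rose and 17 fell of 30 (0 and 26 adjusted over the list alone). Respiratory chain genes passed camera at adjusted p = 2.68e-07 and had adjusted p = 0.530 with an estimated correlation. NDUFS7 had a log2 fold change of -0.75 ± 0.11. In ribosome assembly 15 rose and 1 fell of 29 (17 and 1 adjusted over the list alone). Ribosome assembly genes passed camera at adjusted p = 3.66e-06 and had adjusted p = 0.432 with an estimated correlation. UTP20 had a log2 fold change of 1.27 ± 0.16 and POLR1A, the large subunit of RNA polymerase I, of 0.97 ± 0.12. Of replication genes 14 rose and 1 fell of 35 (21 and 1 adjusted over the list alone). Replication genes passed camera at adjusted p = 5.27e-04 and had adjusted p = 0.628 with an estimated correlation. MCM3 had a log2 fold change of 0.82 ± 0.11 and MCM2 of 0.72 ± 0.12. Of matrix genes 1 rose and 13 fell of 36 (1 and 15 adjusted over the list alone). Matrix genes passed camera at adjusted p = 6.43e-04 and had adjusted p = 0.363 with an estimated correlation. COL1A2 had a log2 fold change of -1.35 ± 0.10 and SPARC of -1.10 ± 0.16. In insulin and growth factor signalling 9 rose and 2 fell of 23 (12 and 2 adjusted over the list alone). The signalling list passed camera at adjusted p = 0.00439 and had adjusted p = 0.716 with an estimated correlation. IRS2 had a log2 fold change of 1.06 ± 0.11 and the receptor MET of 0.98 ± 0.15. Of antioxidant genes 4 rose and 10 fell of 26 (5 and 12 adjusted over the list alone). Antioxidant genes passed camera at adjusted p = 0.0164 and had adjusted p = 0.529 with an estimated correlation. PGD, of the pentose phosphate pathway, had a log2 fold change of -0.94 ± 0.11 and HMOX1 of 1.14 ± 0.12; without 14 d replicate 3 the camera adjusted p was 0.0909 (range over the alternatives 0.0125 to 0.0909). Of immediate-early genes 3 rose and 12 fell of 27 (4 and 14 adjusted over the list alone). Immediate-early genes passed camera at adjusted p = 0.0106 and had adjusted p = 0.562 with an estimated correlation. NR4A1 had a log2 fold change of -2.53 ± 0.23 and EGR1 of -0.98 ± 0.11; without 14 d replicate 1 the camera adjusted p was 0.228 (range 9.68e-04 to 0.228).

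The largest rises at 14 d included KRT1, IVL and FLG, which encode involucrin and filaggrin of the cornified layer of skin, the calcium-binding S100A9 and the cytokine gene IL36B. The list of epithelial markers fixed beforehand did not pass at 14 d, at camera adjusted p = 0.973, and 1 rose and 2 fell of 12 (2 and 2 adjusted over the list alone). KRT5 and KRT14 were on this list but were not tested, because their loci are merged over several coding genes. KRT1 measured 5.00, 97.0 and 94.6 CPM in 14 d replicates 1, 2 and 3 against 0.353 ± 0.159 at 3 d, whereas IL36B measured 195, 169 and 162 against 29.5 ± 2.18. The log2 fold changes were 3.11 ± 0.21 for S100A9, 3.06 ± 0.32 for IVL, 2.71 ± 0.38 for FLG and 2.57 ± 0.12 for IL36B (adjusted p of at most 0.00498). The KRT1 call (adjusted p = 0.0305) was lost without 14 d replicate 2 or 3 (0.0940 and 0.0894) or 3 d replicate 1, 2 or 3 (0.113, 0.0963 and 0.115) and without the filter on low counts (0.0539; range over the alternatives 3.41e-10 to 0.115). The loci that hold KRT5 and KRT14 were looked up after these values were seen. That of KRT5 measured 1.61, 242 and 224 CPM in 14 d replicates 1, 2 and 3, against 1.07 ± 0.0600 at 3 d. That of KRT14 measured 0.876, 141 and 145 CPM, against 0.774 ± 0.101 at 3 d. RNA of other human cells may be present in 14 d replicates 2 and 3, which limits each comparison with 14 d. The other leading rises were CHCHD3, which organises the mitochondrial inner membrane (2.83 ± 0.25), the receptor TIE1 (2.77 ± 0.23) and the antisense transcript IGFL2-AS1 (2.61 ± 0.22), and the leading falls HMGCS1, CSF2, INSIG1, NR4A1, ACAT2, the antisense transcript RUSC1-AS1 (-2.49 ± 0.21), the chaperone DNAJB5 (-2.42 ± 0.39) and the proteoglycan SRGN (-2.29 ± 0.23).

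**Figure D3:**
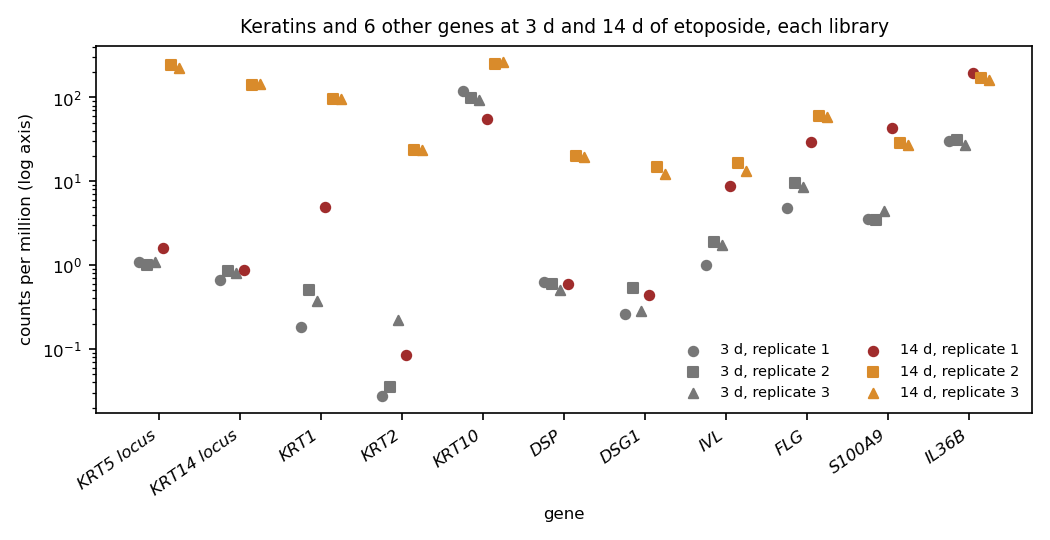
Levels in CPM on a log axis of 11 genes in each library at 3 d and 14 d of etoposide, with a symbol for each replicate. The KRT5, KRT14, KRT1, KRT2, DSP and DSG1 levels of 14 d replicates 2 and 3 lie above those of 14 d replicate 1, which lies near the 3 d libraries for KRT5 at 1.61, while IL36B is high in every 14 d library.

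Of 25719 loci, 3092 were higher and 3104 lower at 14 d (edgeR, adjusted p under 0.05). The total of 6196 became 7583, 3488 and 3756 without 14 d replicate 1, 2 or 3 and 3617, 4926 and 3691 without 3 d replicate 1, 2 or 3. Replicate 1 of 14 d stood apart on the leading principal components, at -28.9 and 72.6 against -82.4 and 0.0979 for replicate 2 and -83.9 and -47.4 for replicate 3. With 14 d replicate 1 alone, an alternative chosen after seeing the data because of the keratins, it was 1526; FOXO3 (adjusted p = 0.174, range over its alternatives 0.001 to 0.174), GDF15 (0.164), IL6 (0.0528), FLG (0.0519), DNAJB5 (0.251), MCM2 (0.0866), MCM3 (0.0503) and NDUFS7 (0.0666) then lost their calls, as did the lists of insulin and growth factor signalling (camera adjusted p = 0.297), replication (0.0652) and antioxidant genes (0.0806). An arm of 1 library has less power by construction: the log2 fold changes of these 8 genes in that fit were 0.37, -1.49, -0.79, 1.95, -2.58, 0.56, 0.65 and -0.61 in the order above, against 0.57, -1.62, -0.79, 2.71, -2.42, 0.72, 0.82 and -0.75 with all 3 libraries. With the length trend removed, the adjusted p of FOXO3 was 0.0537.

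Lists of FOXO target, mitotic, p53 target, interferon, stress response, autophagy, lysosome, glycolysis, homologous recombination, Notch and BMP, astrocyte, neuron, epithelial, blood cell and fibroblast genes did not pass at 14 d (camera adjusted p from 0.184 to 0.973), with sign differences between median, mean and test for p53 target, stress response, lysosome, neuron and epithelial genes. On the interferon list 9 rose and 8 fell of 35 (11 and 8 adjusted over the list alone), and on the stress response list 8 rose and 6 fell of 30 (10 and 8 adjusted over the list alone). Of blood cell markers 0 rose and 1 fell of 11 (0 and 1 adjusted over the list alone). The mitotic list passed with 14 d replicate 1 alone (camera adjusted p = 0.00542, range over the alternatives 0.00542 to 0.917). On the lists that did not pass, STC2 (1.73 ± 0.12), the amino acid transporter subunit SLC3A2 (1.31 ± 0.15), the hexokinase HK2 (1.73 ± 0.13), SQSTM1 (1.04 ± 0.11) and BAMBI (2.15 ± 0.15) rose.

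Loci lower after activation were read in the senescence comparison too. Those lower at 8 h had a median log2 fold change of 0.11 at 14 d and those lower at 16 h 0.10. Their camera adjusted p were 0.0123 and 0.0304, and 0.568 for both with an estimated correlation. Restricted to loci changed at least 2-fold by activation, neither set passed (median log2 fold changes 0.077 and 0.15, camera adjusted p of 0.2001 and 0.0677). Of loci lower at 8 h, 701 were higher at 14 d, against 402 for independent lists (odds ratio 2.35), and of loci lower at 16 h 711, against 417 (odds ratio 2.28). Of loci higher at 8 h and at 16 h, 583 and 629 were lower at 14 d, against 438 and 459 (odds ratios 1.53 and 1.61). Loci lower at 8 h and at 14 d numbered 336, against 412 (odds ratio 0.761), and the remaining pairs of directions had Fisher adjusted p of at least 0.388. The greater power for abundant loci may add to each excess here too. Loci higher at 8 h and at 16 h did not pass as sets (camera adjusted p of 0.453 and 0.376).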

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

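No test in this part was chosen after its result was seen, but examples of lists whose calls held without single libraries were preferred after values were seen, so the losses named here do not measure how often calls are lost. Levels differed between 8 h and 16 h of activation by a direct test of the 2 times, with 2771 loci called (edgeR, adjusted p under 0.05). The sample titles give no induction time for GFP. A change in the FOXO3 effect therefore cannot be told apart from time in doxycycline or in culture. The values below are log2 fold changes of 16 h against 8 h, and medians for lists.

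Lists that differed by the camera test at the preset correlation, none of which held with an estimated correlation, were replication (-0.41), mitosis (-0.15), secreted factors of senescence (0.23), autophagy (0.11), lysosome (0.092), ribosome assembly (-0.28), homologous recombination (-0.19), matrix (-0.36), neuron markers (-0.33) and immediate-early genes (0.28).

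Among genes named in the results, those higher at 16 h were IL1B (3.19), TPPP (2.92), IL6 (2.27), CSF3 (2.25), IGFBP1 (2.05), CARNS1 (2.00), CYP24A1 (1.98), MAP3K4-AS1 (1.79), LIF (1.71), DEPP1 (1.46) and DUSP1 (1.14), and by less FOSL1 (0.91), IGFBP3 (0.83), ATP6V0D2 (0.82), AHDC1 (0.80), EPHA2 (0.76), DUSP7 (0.75), GLUL (0.72), LRFN4 (0.70), SQSTM1 (0.61), CCNE1 (0.60) and CTSB (0.55). Those lower at 16 h were SNX22 (-6.71), ANKRD30B (-2.86), FLRT3 (-2.81), EPHA5 (-2.29), RORB (-2.16), TMEM74 (-2.12), SLITRK6 (-2.07), NDST4 (-2.00), NFATC2 (-1.43), MAP2 (-1.29), SESN1 (-1.21) and SNAP25 (-1.18), and by less LOXL1 (-1.08), FOXO3 (-0.94), COL5A2 (-0.94), BRIP1 (-0.88), COL5A1 (-0.85), ATM (-0.80), SOX9 (-0.80), MCM2 (-0.70), BARD1 (-0.68), CCNA2 (-0.61), EGR1 (-0.60) and FASN (-0.43). SNX22, IL6 and SOX9 lost their calls without single libraries, SOX9 without 8 h replicate 2 (adjusted p = 0.0523, range 2.53e-04 to 0.0523). SNX22 was already low in 8 h replicate 2.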

How the results depend on the processing

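The alternatives of values divided by 4, the length trend, the knockdown libraries as deposited, the renumbered block and 14 d replicate 1 alone are tests chosen after seeing the data. Requiring at least 2-fold left 2459, 2223, 572, 5978 and 2123 loci at 8 h, 16 h, 16 h against 8 h, knockdown and senescence, by construction fewer than 6685, 6900, 2771, 11713 and 6196. With an estimated correlation 2, 5, 0, 0 and 0 lists passed in place of 8, 13, 10, 14 and 10; fry, which asks a different question, passed 19 at 8 h and 22 at 16 h. Leaving out single libraries gave 5283 to 5956 loci at 8 h, 5552 to 6889 at 16 h, 1597 to 2947 for 16 h against 8 h, 9285 to 10969 for knockdown and 3488 to 7583 for senescence, with fewer samples by construction; where a single library stayed in an arm, it was assumed to vary like the others. For 16 h against 8 h the lists called ranged from 6 to 11 when a library was left out. With 14 d replicate 1 alone the senescence count was 1526.

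Sets of loci at least 2-fold changed by activation moved otherwise in the knockdown: loci higher at 8 h had a median log2 fold change of 0.50 (adjusted p = 0.00180) and loci higher at 16 h 0.48 (adjusted p = 0.00235), both now called, while the median of loci lower at 16 h turned from -0.18 to 0.15 (adjusted p = 0.334); the cause was not tested. With an estimated correlation the value of -0.18 for loci lower at 16 h lost its call (adjusted p = 0.140). In senescence, loci lower at 8 h (0.11) and at 16 h (0.10) lost theirs with an estimated correlation (adjusted p = 0.568 for both) and, as sets of at least 2-fold, stood at 0.077 (adjusted p = 0.2001) and 0.15 (adjusted p = 0.0677); the cause was not tested.

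The replicate numbers did not pair the libraries: same-numbered libraries correlated in their deviations by -0.00757 to 0.0279 in the activation table, 0.0450 to 0.0507 in the knockdown table and -0.0293 to 0.00624 in the senescence table. A replicate block called 6244, 6478, 2308, 10236 and 5765 loci in the order above, and 9780 for knockdown with the identical library given number 2. Under the block these were called: BCL2L11 at 8 h (adjusted p = 0.0262) and 16 h (0.0372), fibroblast markers at 16 h (0.0428), and MYC (0.00464) and blood cell markers (2.18e-04) after knockdown. The block ended the calls of SNX22 between the times (0.130), HMGB2 at 14 d (0.0554) and glycolysis genes after knockdown (0.118, and 0.122 with the number 2). Ranges over all alternatives, block included, were 0.00175 to 0.152 and 0.0210 to 0.267 for BCL2L11, 0.00464 to 0.766 for MYC, 2.18e-04 to 0.301 for blood cell markers and 5.08e-06 to 0.139 for SNX22. DESeq2 called 7443, 7542, 3681, 12612 and 7003. The knockdown count was 14060 with all 6 libraries as deposited. The median log2 fold change of all knockdown loci was 0.062, 0.083 with DESeq2 size factors in edgeR, which change the scaling alone, and 0.22 with the DESeq2 Wald test, 0.18 without the filter and 0.16 with the length trend removed, which change more than the scaling. Groups did not overlap in 48.2%, 45.1%, 34.5%, 70.0% and 43.4% of loci, where chance alone gives 10% for 3 against 3 and 20% for 2 against 3. In the simulated counts of the senescence comparison edgeR called 39% of 2-fold and 4% of 1.5-fold changes, and DESeq2 79% and 25%. Far fewer loci changed in the simulations than were called in the data. Their rates of recovery and of false calls therefore do not describe the real comparisons. A change that edgeR did not call at 14 d can still be real. Of the calls DESeq2 made on simulated counts, 29.8%, 23.2%, 27.9%, 42.8% and 32.7% were false in the order above, against 12.2% for edgeR in senescence.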

Other observations

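The tests of the reversed response, the library deposited under 2 numbers, the length trend, the skin cell RNA, the background level per locus and background at changes of at least 2-fold were chosen only after the results were seen. IL36B, a cytokine gene that rose at 14 d of etoposide, was also higher after FOXO3 shRNA, at 43.2 ± 2.28 against 9.35 ± 1.09 CPM (edgeR, log2 fold change 2.21 ± 0.11, adjusted p = 4.59e-05, n = 2 against 3), and stood at 5.37 against 5.30 CPM at 8 h of activation (adjusted p = 0.963) and 8.00 CPM at 16 h (adjusted p = 0.0464, called). S100A9 stood at 3.82 ± 0.140 against 0.105 ± 0.183 CPM after FOXO3 shRNA and was not called (adjusted p = 0.0526). Both were looked up after their values at 14 d were seen. CDKN2A, CDKN2B and MTAP, which neighbour each other and are known as deleted in U87MG, had 0 counts in 14 d replicate 1 and in each 3 d library. In 14 d replicates 2 and 3 they had 21 and 28, 93 and 116, and 20 and 33 counts.

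For the 4 comparisons of 3 against 3 libraries, 10 splits are too few for a share under 0.05. The real split called 6685 loci at 8 h against a highest other of 1, 6900 at 16 h against 3, 2771 for 16 h against 8 h against 3, and 6196 for senescence against 0; in each, 1 split, the real one, gave as many.

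The first pattern is the breadth of the knockdown response, 11713 called loci beside a FOXO3 level that fell by 0.53 on the log2 scale. A reversal of the activation response is argued against, since 57.6% of the 4110 loci called in both changed in the same direction (56.8 to 57.8% without single libraries). The count was made with the identical library counted once, so its double deposit could not account for it. Counting that library under both its numbers changed the count by a ratio of 1.2004. Removing the length trend changed the count by a ratio of 0.998, so that trend does not account for it. Silent loci are genes of odorant and taste receptors, keratin-associated proteins and beta-defensins, taken as silent in this cell type. Background reads add counts and are argued against for falls of at least 2-fold, 40.3% of the changes of that size (2408 loci), while the 171 silent loci rose by 2.00 CPM in sum. For rises, background reads could account for a part that stays open. Silent families stood 1.30 times as high, between the bounds set beforehand. Of the 3570 rises of at least 2-fold, 44.0% were over 2 times the largest silent rise, that of KRTAP2-3. The 68.7% called of 11111 loci of mean CPM of at least 5 decides nothing, as abundant loci have more power. An effect of the hairpin other than on FOXO3, and a difference between the cultures, stay open and untested.

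The second pattern is the fall of ribosomal protein genes after knockdown and at 14 d of etoposide. With the length trend removed their median log2 fold change was -0.86 from -1.02 after knockdown and -0.63 from -0.73 at 14 d. Other coding genes in the same ranges of length and abundance had a median of -0.18 over 3155 genes after knockdown and -0.053 over 2555 at 14 d. Length was the median over the annotated transcripts of a gene, and these genes shared the ranges of the list but not its distribution. Length bias by this measure and a general fall over these ranges are thus argued against as the whole cause. A fall of the shortest and most abundant transcripts as a class stays open. A biological fall in these transcripts with FOXO3 shRNA or time in etoposide stays a hypothesis, and RNA quality and reads shared with pseudogenes were not tested as causes.

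The third pattern is the rise of KRT1, IVL, FLG, S100A9 and IL36B at 14 d of etoposide, set beside keratins chosen after these values were seen. Of these keratins, KRT5 and KRT14 were on the epithelial list fixed beforehand but were not tested there. In replicates 2 and 3 the loci of KRT10, KRT5 and KRT14 rose by a median of 159% of the rise of KRT1. These were also the only libraries of this experiment with counts, though low, of CDKN2A, CDKN2B and MTAP, known as deleted in U87MG. RNA of other human cells, such as skin cells, may thus be present in these libraries. In replicate 1 IVL stood at 58.6%, FLG at 48.8%, S100A9 at 157% and IL36B at 118% of replicates 2 and 3 (median 88.3%) and the loci of KRT5, KRT14, KRT1 and KRT2 at a median of 0.651%, with KRT1 at 5.22% and 14.2 times its 3 d mean and KRT10 at 21.6% and 0.532 times. Such RNA in proportion to these keratins is thus argued against as the whole source of the 4 genes in replicate 1, while a part of IVL and FLG in replicates 2 and 3 stays open. The smallest mean rise of the 4 genes at 14 d was 2.83 times the largest of any silent locus, DEFB103A (4.01 CPM). This gene may have responded, so the bound may exceed the background. Background reads stay open in replicate 1, with IVL at 8.77 against 1.54 CPM at 3 d and the highest summed level of silent families. That level alone decides nothing (1.13 times 3 d, 14 d libraries 0.938 to 1.48 times). A response to etoposide time stays a hypothesis.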
